A study of Brassica carinata with 12 samples.

How the data were processed

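RNA-seq was done on young anthers of synthetic Brassica carinata, an allotetraploid mustard that carries the B genome of B. nigra and the C genome of B. oleracea. Per the labels, a haploid form with 1 B and 1 C set came from a cross of B. oleracea var. alboglabra with B. nigra, and a tetraploid form was obtained with ovule culture and colchicine. Anthers were labelled as at meiosis (sporogenesis) or at mitosis (gametogenesis), and 3 libraries were given for each of the 4 groups, 12 in all. The labels name the anther as the tissue, while the extraction protocol speaks of floral buds. Nothing in the labels says that the libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical. No batch or date is given.

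The deposited count table holds whole-number read counts per gene, not normalised, which the values themselves show. The deposited FPKM table holds FPKM values for the same genes and libraries, and the tool that made it is not given in the sources used here. Per the submitters' processing notes, HISAT2 2.1.0, Bowtie2 2.2.3, TopHat2 and featureCounts 2.0.1 were named, with no role or order. The genome build, the annotation, the strand setting and the treatment of reads that map to both subgenomes are not given in the sources used here. Each table has 97149 genes. The gene IDs place 37470 genes on 8 B chromosomes and 52279 on 9 C chromosomes, and 7400 are unplaced. Column names of 2 libraries in the FPKM file differ from the titles in letter case only, and 1 gene ID carries an extra ending. Counts and FPKM differ at low values. Between 3041 and 3338 genes per library had a count of 0 and an FPKM above 0, and between 447 and 662 had the opposite.

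The total count per library ranged from 15769687 to 16793767. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. For a gene with 0 counts in a group, the fold was computed against a floor of 3 counts per library and is a lower bound. For a gene with 1 to 3 counts in a group, an exact 95% binomial counting interval is given. Between libraries of a group, log2 values across genes had Pearson's r of 0.976 to 0.982, and the mean chi-square per gene was 2.52 to 3.08 for genes with at least 20 counts in a pair, so no pair agreed within sampling noise and every library was counted as 1 replicate.

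Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors (which also scale the CPM, except in the number of genes with at least 1 CPM), its default filter on low counts, 1 model over all 12 libraries with a mean per group, and the two-sided quasi-likelihood test. P-values were adjusted by Benjamini-Hochberg over the 51860 genes tested, which hold 99.8% of all counts, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.0839. Contrasts were haploid against tetraploid at each stage, mitosis against meiosis in each form, their interaction, and the ploidy contrast averaged over stages. Standard errors are the log2 fold change divided by the square root of F. Chromosomes were tested as gene sets with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 108 tests. Shares of counts per library were compared with exact two-sided permutation tests. With 3 libraries against 3 the smallest possible p is 0.1, and permuting ploidy within stages gives 400 arrangements and a smallest p of 0.005. Runs of 50 consecutive tested genes followed the order of the gene IDs, and their extremes were set against 1000 shuffles of genes outside chromosome C03.

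The count test was tested on simulated data with 50 genes changed at each size. For the meiosis comparison (50892 genes in that step) it recovered 50.0% of genes changed 1.5-fold, 60.0% at 2-fold, 94.0% at 4-fold and 96.0% at 8-fold, with 5 false calls. For the mitosis comparison (50926 genes) it recovered 66.0%, 76.0%, 100% and 98.0%, with 6 false calls. The changed genes were drawn only from genes above a minimum mean count, so recovery at lower counts was not tested. Few genes were changed, while the real comparisons called 38.3% (meiosis) and 47.7% (mitosis) of genes. The rates of recovery and of false calls may therefore differ in the data.

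The contrasts, the share of counts from B-subgenome genes, the rule for named genes and most alternatives were fixed before the data were examined. The chromosome, gene-run and stage-class summaries were chosen after seeing the data. The files do not pair gene IDs with names, and no reference was used here. The planned gene lists and the term enrichment were therefore not run, and at most 2 IDs that rose and 2 that fell are given per comparison. These have the largest fitted log2 fold changes among genes that were called, averaged at least 10 CPM in the higher group and had non-overlapping libraries. Homoeologous and other near-identical copies may share reads, so the values of single genes are uncertain to that extent. Alternatives were size factors by the median of ratios, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes of at least 0.5 FPKM in 3 libraries, a replicate block, a 2-fold minimum, only the libraries compared, and each library left out in turn.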

Results

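Young anthers of synthetic haploid and tetraploid Brassica carinata were profiled by RNA-seq at 2 stages of male development, meiosis and mitosis. Each of the 4 groups had 3 libraries, with total counts between 15769687 and 16793767 per library. Fold changes are given on the log2 scale with their standard error (SE), and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Expression levels are CPM (counts scaled to library size) as mean ± SD (n = 3). The chromosome of a gene is read from its ID, since the files give no coordinates and do not pair IDs with gene names.

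The first comparison asked which genes differed between haploid and tetraploid anthers at meiosis. Genes on chromosome C03 were higher in the haploid as a group, with a median log2 fold change of 0.83 over 2554 tested genes (interquartile range 0.41 to 1.25), or 1.78-fold. On C03, 1631 genes were called higher and 53 lower. The medians of the other 16 chromosomes lay between -0.04 and 0.00. TMM scaling brings the bulk of genes near 0, so all fold changes are relative to the other genes. A shift shared by all genes would not be seen. Of the 51860 genes tested, 10096 were called higher in the haploid and 9774 lower, and 2790 and 2115 of these changed at least 2-fold. Outside C03, 8465 genes were called higher and 9721 lower. This larger side turned when C03 genes were left out before the fit, at 9010 higher and 8894 lower. The larger side of the split over all genes turned with the deposited FPKM values and limma-trend (pseudocount 1), at 9711 higher and 9721 lower.

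C03 stood apart from the other chromosomes in the gene-set test (camera, adjusted p = 3.85e-30). The call held with an estimated correlation (adjusted p = 4.03e-10), under which 7 of the 18 sets passed at this stage. Every run of 50 consecutive C03 genes had a median above 0, from 0.52 to 1.12 over 51 runs. The 889 runs on other chromosomes had medians from -0.34 to 0.45. The highest of them, from BcaB05g21642 to BcaB05g21722 on B05, was the 1 run that passed the level below which 95% of the highest medians in 1000 shuffles of the genes lay (0.34), and it was singled out after its value was seen. C03 genes took 4.38% ± 0.0124 (SD, n = 3) of counts in the haploid and 2.56% ± 0.0142 in the tetraploid at meiosis. Among the most abundant C03 genes, 69 with over 64 CPM, the median was 0.64, and among 808 genes at 4 to 16 CPM it was 0.83. Genes outside C03 had medians of -0.17 and 0.02 at these levels.

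**Figure D1:**
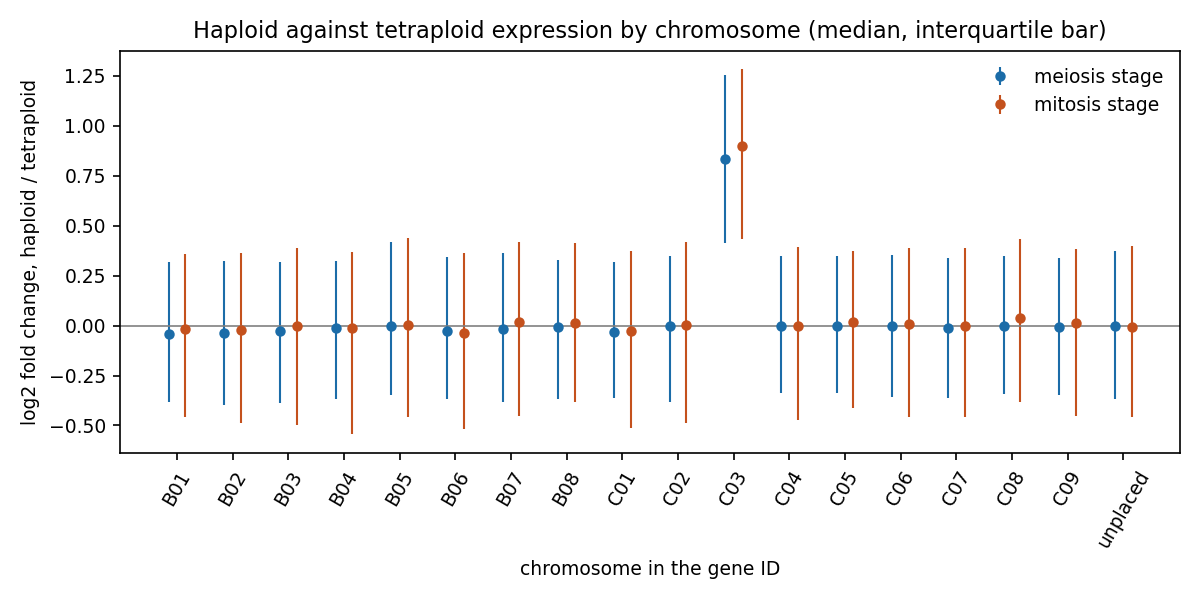
Log2 fold change of haploid over tetraploid anthers (vertical axis) for the tested genes of each chromosome and the unplaced genes (horizontal axis). Points are medians and bars interquartile ranges, in blue at meiosis and orange at mitosis. C03 sits at 0.83 and 0.90, and the other 16 chromosomes lie within 0.0428 of 0.

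Among single genes, BcaC08g43483 on C08 reached 29.8 ± 4.43 CPM in the haploid at meiosis and had 0 counts in all 3 tetraploid libraries, at least 174-fold higher (adjusted p = 1.14e-25, edgeR). BcaB03g12879 on B03 stood at 20.9 ± 1.64 CPM against 0 counts, at least 122-fold higher (adjusted p = 3.67e-26, edgeR). Both genes were far more abundant at mitosis, where BcaC08g43483 reached 1442 ± 52.5 CPM in the haploid and 742 ± 28.1 CPM in the tetraploid. BcaB02g06569 on B02 fell to 1.02 ± 0.104 CPM in the haploid from 25.2 ± 0.231 CPM in the tetraploid (log2 fold change -4.62, SE 0.19, adjusted p = 5.94e-20, edgeR). BcaB01g02594 on B01 was at 2.95 ± 0.640 against 35.2 ± 1.29 CPM (-3.57, SE 0.07, adjusted p = 1.06e-28, edgeR). At mitosis BcaB01g02594 was also far more abundant, at 4296 ± 55.2 CPM in the haploid and 4774 ± 71.3 CPM in the tetraploid. BcaB02g06569 was less abundant there, at 0.175 ± 0.0983 and 1.35 ± 0.377 CPM.

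The same question was asked at mitosis. C03 genes were again higher in the haploid, with a median of 0.90 (interquartile range 0.43 to 1.28), or 1.86-fold. With the deposited FPKM values the median was 0.56 on the log2(FPKM + 1) scale and 0.81 on the log2(FPKM + 0.1) scale. On C03, 1688 genes were called higher and 166 lower, and the other 16 chromosomes had medians from -0.04 to 0.04. Of all genes tested, 12087 were called higher in the haploid and 12676 lower. Changes of at least 2-fold were more often decreases, with 3993 genes higher and 6219 lower. Outside C03 the counts were 10399 higher and 12510 lower.

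The C03 set was called at this stage too (camera, adjusted p = 2.2e-22, and adjusted p = 9.06e-10 with an estimated correlation, under which 7 of the 18 sets passed). Medians of its 51 gene runs ranged from 0.59 to 1.12, against -0.42 to 0.34 for 889 runs elsewhere, of which 0 passed the shuffle level of 0.39. The C03 share of counts was 5.63% ± 0.0355 (SD, n = 3) in the haploid and 2.88% ± 0.00577 in the tetraploid. Over both stages the difference in this share was the largest of all 400 arrangements of ploidy within stages (exact two-sided permutation p = 0.005, the smallest possible, and 0.00571 after adjustment over 8 measures). C03 genes were higher in each of the 6 haploid libraries than the mean of the tetraploid libraries of their stage.

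**Figure D2:**
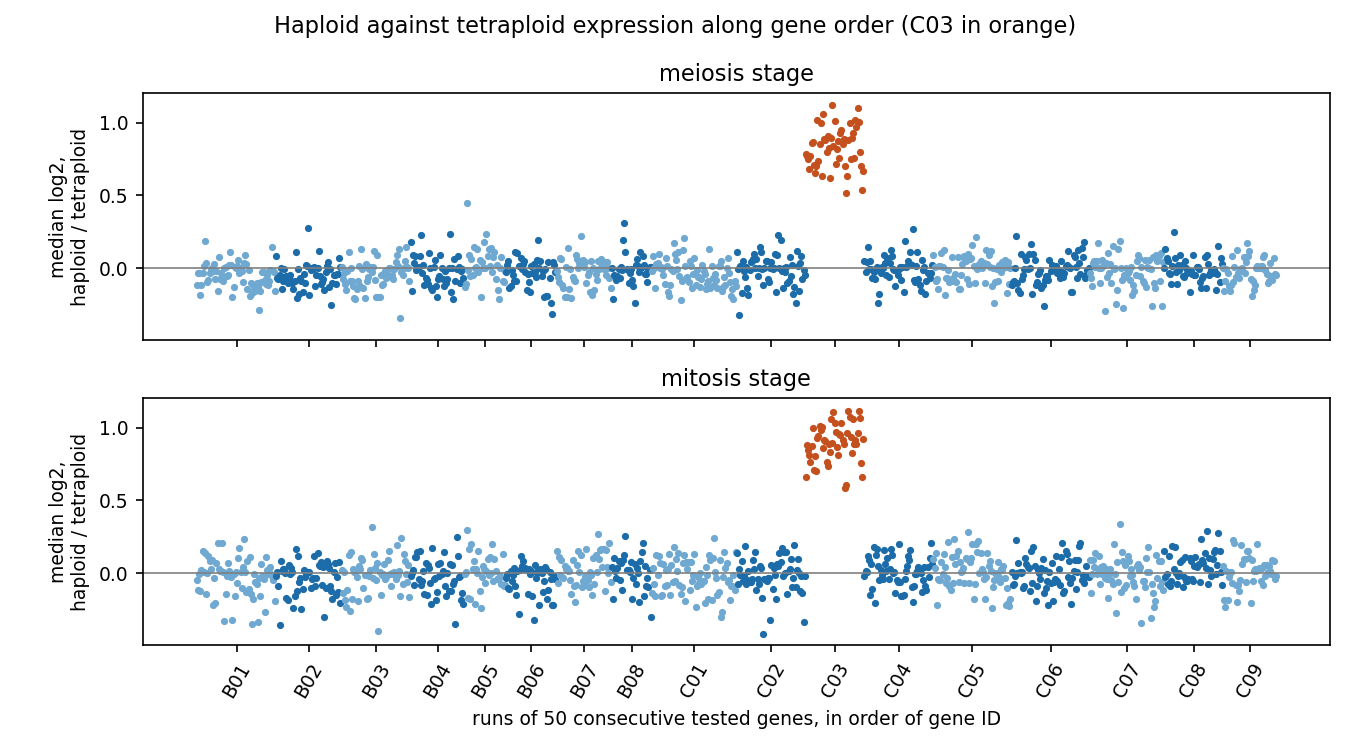
Median log2 fold change of haploid over tetraploid anthers (vertical axis) for runs of 50 consecutive tested genes in the order of their IDs (horizontal axis), at meiosis (top) and mitosis (bottom). Each point is 1 run, with C03 in orange. All 51 runs on C03 lie above the 889 runs on other chromosomes at both stages.

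Genes that rose steeply between the stages were lower in the haploid at mitosis. Outside C03, 3776 genes rose more than 16-fold from meiosis to mitosis in the tetraploid, and their median in the haploid against the tetraploid at mitosis was -1.88 (interquartile range -2.59 to -0.49). Of these, 2763 were called lower in the haploid and 446 higher. The median was also -1.88 with the 47 genes at 0 counts in the haploid set at their bound. Because the class and the difference share the tetraploid mitosis libraries, the class was also defined from 1 such library. The difference was then taken from the remaining libraries. These classes of 2754 to 2797 genes, measured on log2 CPM with a prior count of 2, gave -1.90 to -1.87. Simulated libraries with no ploidy effect gave -0.00159 over a class of 2721 genes. Classed by the change in the haploid, 2627 genes had a median of -1.59. Genes within 0.25 between stages in the tetraploid had a median of 0.01. The 1838 genes that fell more than 16-fold in the tetraploid had a median of 1.46, with 695 called higher in the haploid and 66 lower, or 1.17 with genes at 0 counts set at their bound and 519 without a fold left out. Classed by 1 tetraploid mitosis library and compared with the others, 1255 to 1278 genes fell more than 16-fold. Their median was 0.62 to 0.65, also on log2 CPM. Over 1482 genes classed by the haploid it was 0.01, where the class and the difference share the haploid mitosis libraries.

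**Figure D3:**
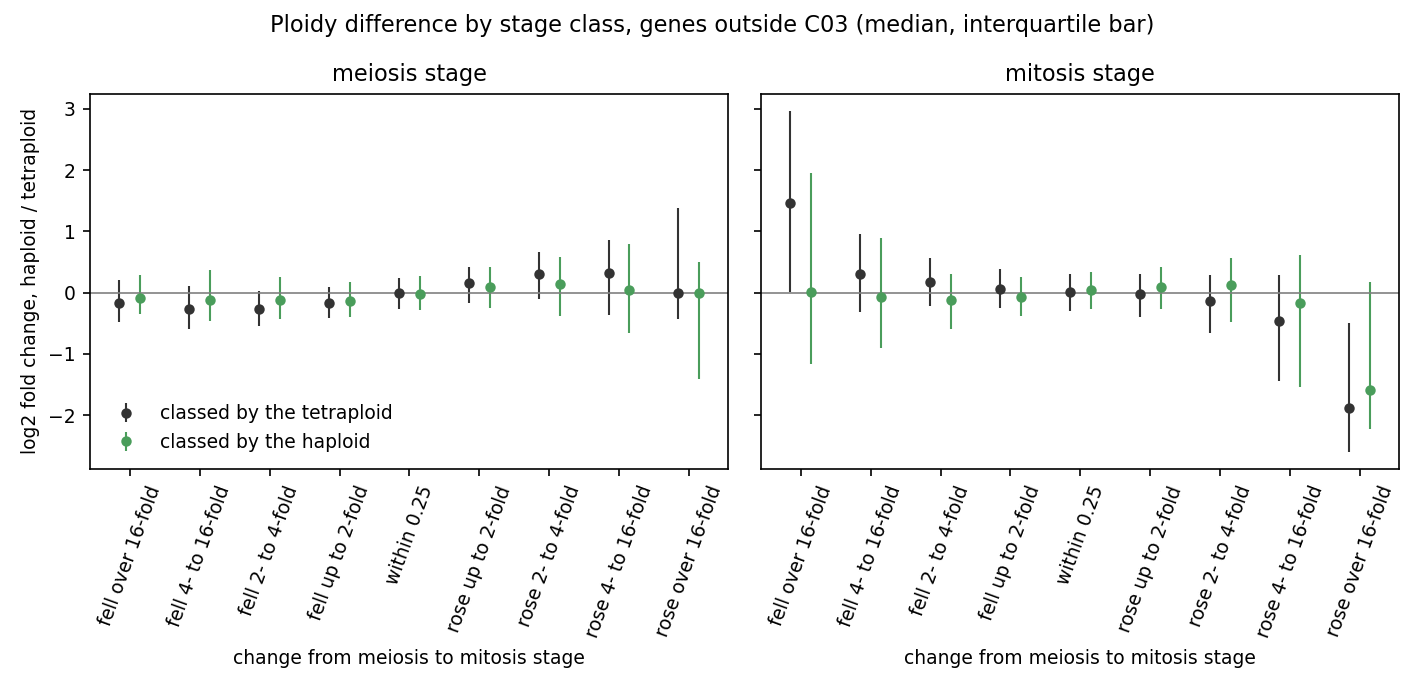
Log2 fold change of haploid over tetraploid anthers (vertical axis) for genes outside C03, in classes of their change from meiosis to mitosis (horizontal axis), at meiosis (left) and mitosis (right). Points are medians and bars interquartile ranges, with classes set by the tetraploid in black and by the haploid in green. The class that rose more than 16-fold lies at -1.88 and -1.59 at mitosis.

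The decreases with the largest fitted fold change at mitosis were in genes with 0 counts in all haploid libraries, where the fitted size depends on the prior count and only a lower bound can be given. BcaB04g20210 on B04 stood at 29.3 ± 3.70 CPM in the tetraploid at mitosis and was at least 147-fold lower in the haploid (adjusted p = 2.24e-19, edgeR). BcaC07g38151 on C07 stood at 26.4 ± 3.77 CPM and was at least 133-fold lower (adjusted p = 9.2e-19, edgeR). Both had 0 counts in all libraries at meiosis. BcaC02g08516 on C02 was higher in the haploid, at 12.1 ± 0.780 against 0.0653 ± 0.0648 CPM. The tetraploid value rests on 3 counts, and the ratio was 185 (counting interval 62.9 to 899). BcaC01g06148 on C01 was at 17.8 ± 1.11 against 0.132 ± 0.133 CPM (log2 fold change 7.01, SE 0.22, adjusted p = 6.84e-24, edgeR).

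Ploidy calls were compared between the stages, which share no library but share 1 model and its estimate of the spread. Genes with high counts or a low spread can be called more readily at both stages. Independent lists are therefore only a rough reference, here and for the stage comparisons below. Higher in the haploid at both stages were 5025 genes, where independent lists would share 2353, and lower at both were 4142, against 2389. Opposite calls were made for 2807 genes, against 4746. Outside C03, 3692 genes were higher at both stages (1785 for independent lists) and 4120 lower (2466). Ploidy fold changes of the stages correlated only weakly across genes, with Pearson's r of 0.235 and Spearman's rho of 0.284. Outside C03 these were 0.202 and 0.242. Averaged over stages, 12707 genes were called higher in the haploid and 11757 lower. Which side was larger depended on the method, since median-of-ratios size factors gave 11961 higher and 12409 lower, DESeq2 11137 and 11971, FPKM with limma-trend (pseudocount 1) 12399 and 15518, and a 2-fold minimum 2835 and 3155. BcaC03g17637 on C03 rose, from 0 counts in the tetraploid to 11.4 ± 1.46 CPM at meiosis and from 62.6 ± 7.13 to 727 ± 20.14 CPM at mitosis. BcaB01g00503 on B01 had 0 counts in the tetraploid and 13.7 ± 1.51 CPM in the haploid at meiosis, and 65.6 ± 1.14 and 498 ± 9.43 CPM at mitosis. BcaC05g25887 on C05 fell (log2 fold change -5.58, SE 0.23, adjusted p = 3.85e-20, edgeR), and BcaB04g21137 on B04 was at 0 counts in the haploid at mitosis against 10.5 ± 1.34 CPM.

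The next comparisons asked which genes changed from meiosis to mitosis within each form. The tetraploid changed more genes, with 19322 called higher at mitosis and 18000 lower, and 12606 and 9880 of these by at least 2-fold. In the haploid 17292 were higher and 15770 lower, and 10220 and 7978 by at least 2-fold. Both forms moved many genes together, with 14121 higher in both (6443 for independent lists) and 12955 lower in both (5474). Only 1185 genes were called in opposite directions, against 11877. Fold changes of both forms correlated across genes, which are not independent replicates, with Pearson's r of 0.886 and Spearman's rho of 0.828. With the deposited FPKM values and limma-trend (pseudocount 1) the larger side turned in both forms, to 14058 genes higher and 21536 lower in the haploid, 39.5% higher against 52.3% with counts, and to 17883 higher and 22521 lower in the tetraploid, 44.3% against 51.8%.

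In the haploid, BcaB01g06051 on B01 rose from 0 counts to 2366 ± 122 CPM, at least 13709-fold (adjusted p = 1.93e-42, edgeR). BcaC06g32427 on C06 rose from 0 counts to 1818 ± 131 CPM, at least 10532-fold (adjusted p = 2.03e-40, edgeR). BcaC01g03010 on C01 fell from 46.3 ± 2.98 CPM to 0 counts, at least 233-fold lower, and BcaB04g19173 on B04 from 36.1 ± 2.15 CPM to 0 counts, at least 182-fold lower. In the tetraploid, BcaC01g04295 on C01 rose from 0 counts to 1109 ± 28.9 CPM, at least 6479-fold, and BcaC05g25911 on C05 from 0 counts to 1073 ± 19.8 CPM, at least 6270-fold. At mitosis BcaC01g04295 stood at 214 ± 9.32 CPM in the haploid. BcaC01g00670 on C01 fell from 502 ± 16.1 to 0.0216 ± 0.0374 CPM, which rests on 1 count (ratio 23097, counting interval 4145 to 912306), and BcaC05g30108 on C05 from 73.9 ± 3.52 CPM to 0 counts, at least 377-fold lower. C03 genes had median stage changes of 0.06 in the haploid and 0.00 in the tetraploid, and the set was called in neither (camera, adjusted p = 0.998 each, and adjusted p = 0.303 and 0.619 with an estimated correlation). The C03 share of counts at mitosis was 1.29 times that at meiosis in the haploid and 1.13 times in the tetraploid (exact permutation p = 0.1 each, the smallest possible with n = 3).

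Whether the ploidy difference itself differed between stages was tested as an interaction. It was called for 15813 genes, 8077 with a more positive difference at mitosis and 7736 with a more negative one. The larger side turned with median-of-ratios size factors (7450 and 8262), DESeq2 (6667 and 7670), FPKM with limma-trend at a pseudocount of 1 (7940 and 11070), no filter on low counts (7960 and 7965) and a 2-fold minimum (3033 and 3878). It also turned without haploid mitosis replicate 2 (7196 and 7469) or haploid mitosis replicate 3 (7265 and 7532). C03 genes had a median interaction of 0.04 (camera, adjusted p = 0.998, and adjusted p = 0.0238 with an estimated correlation). BcaB05g21637 on B05 rose in the tetraploid to 34.7 ± 3.86 CPM at mitosis and stayed at 0.110 ± 0.0745 CPM in the haploid (adjusted p = 1.3e-11, edgeR). BcaC09g50824 on C09 reached 15.7 ± 0.678 CPM in the tetraploid at mitosis and had 0 to 3 counts in every other library (adjusted p = 4.44e-05, edgeR). Its call was lost without haploid meiosis replicate 2, which holds its 3 counts at meiosis (adjusted p = 1, edgeR). BcaC05g24525 on C05 and BcaC02g12720 on C02 fell to 0 counts in the tetraploid at mitosis and to 1.42 ± 0.841 and 1.15 ± 0.192 CPM in the haploid, from 14.99 ± 0.331 and 24.8 ± 2.13 CPM in the tetraploid and 12.2 ± 1.66 and 21.4 ± 2.91 CPM in the haploid at meiosis.

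The balance of the B and C subgenomes was compared as the share of placed counts from B genes. At meiosis it was 45.1% ± 0.0248 (SD, n = 3) in the haploid and 45.5% ± 0.00326 in the tetraploid, and at mitosis 44.3% ± 0.1001 and 45.3% ± 0.0235. Differences of haploid minus tetraploid were -0.441 and -0.975 percentage points, and of mitosis minus meiosis -0.761 in the haploid and -0.227 in the tetraploid (exact two-sided permutation p = 0.1 each, the smallest possible with n = 3). Over both stages haploid minus tetraploid was -0.708 percentage points (exact two-sided permutation p = 0.005 over 400 arrangements within stages, the smallest possible, and 0.00571 after adjustment over 8 measures). With C03 genes left out, the ploidy difference reversed at both stages. The B share was then 47.3% ± 0.0321 in the haploid and 46.8% ± 0.00392 in the tetraploid at meiosis, and 47.2% ± 0.0906 and 46.8% ± 0.0264 at mitosis. The differences of mitosis minus meiosis shrank to -0.0868 percentage points in the haploid, where libraries of the stages then overlapped (exact permutation p = 0.3), and to -0.0539 in the tetraploid (exact permutation p = 0.1).

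**Figure D4:**
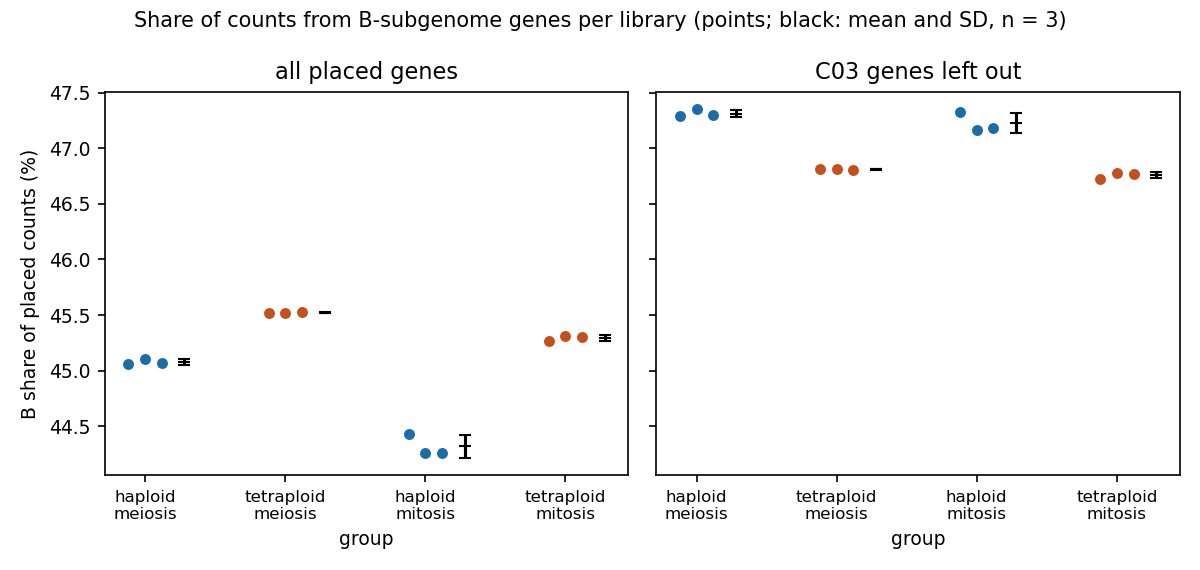
Share of placed counts from B-subgenome genes in percent (vertical axis, which does not start at 0) per library and group (horizontal axis), for all placed genes (left) and without C03 genes (right). Points are libraries, and black marks give the mean and SD (n = 3). The haploid lies below the tetraploid on the left and above it on the right.

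Transcript abundance was also more concentrated in the haploid. The 100 most abundant genes of a library took 15.7% ± 0.161 (SD, n = 3) of counts in the haploid and 12.2% ± 0.0360 in the tetraploid at meiosis, and 19.96% ± 0.243 and 16.2% ± 0.113 at mitosis (exact permutation p = 0.005 within stages, adjusted p = 0.00571). On total counts without TMM factors, genes with at least 1 CPM numbered 43061 ± 226 in the tetraploid at mitosis and 41355 ± 235 in the haploid (exact permutation p = 0.1, n = 3, the smallest possible). At meiosis they numbered 41357 ± 66.0 and 41303 ± 189, a difference within the spread between libraries (exact permutation p = 0.9). Over both stages haploid minus tetraploid was -879.7 genes (exact permutation p = 0.045 within stages, and 0.045 after adjustment over 8 measures). On this scale the larger share of the top genes in the haploid leaves fewer counts for its other genes, which may lower its number.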

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

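The tests of C03, of the steeply rising genes and of the late genes at meiosis were chosen after the result was seen, as was the final way to draw the splits for the interaction and for the average over stages, which replaced an earlier draw after its result was seen.

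The ploidy difference differed between stages for 15813 genes by the interaction test, 8077 towards higher and 7736 towards lower in the haploid at mitosis, and which of these was larger changed with the method (6667 and 7670 with DESeq2, 7940 and 11070 with FPKM and limma-trend). The genes at its extremes had fitted log2 interactions of 7.85 (BcaC05g24525), 7.46 (BcaC02g12720), -12.13 (BcaC09g50824) and -10.98 (BcaB05g21637). All but BcaB05g21637 have a group at 0 counts, so these 3 fitted sizes depend on the prior count. Of 100 splits of the libraries within stages, drawn from 200, 1 gave as many interaction calls, the real one, and the highest other gave 8109. For the average over stages it was also 1 of 100, with 24464 calls against 8121. By this draw a chance division of these libraries would rarely give as many calls for the average. It cannot speak to chance differences between plants, since the libraries of a group may be technical. For both contrasts the splits bear only on whether ploidy had an effect at any stage. They do not show whether that effect was shared by the stages or differed between them. The high values came from splits that kept the real division at 1 of the stages, and the 84 drawn splits that kept it at neither gave 0 calls (up to 1097 and 1072 genes at an unadjusted p under 0.05, edgeR; no other tool was run on splits). Exchanging the ploidy labels at 1 stage only, a split that was not drawn, turns the interaction into the averaged contrast, with its 24464 calls. For the 4 comparisons of 3 against 3 libraries, 1 of 10 splits gave as many calls, the real one, with 19870, 24763, 33062 and 37322 calls against a highest other of 0 (up to 1948, 1686, 1185 and 746 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05.

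C03 genes were 1.78-fold and 1.86-fold higher in the haploid (log2 medians of 0.83 and 0.90, and 0.56 at each stage on the log2(FPKM + 1) scale). Library scaling would shift other chromosomes by the same amount, but their largest absolute median was 0.0428 (0.04 on the log2 scale). TMM itself brings the bulk of genes near 0, so only the gap to C03 bears on scaling. A few abundant genes would leave most gene runs near 0, but the lowest run of 50 C03 genes had a median of 0.52. The C03 level lay 0.87 below the mean of the other C chromosomes in the tetraploid at meiosis (difference -0.87, 11.5 SD of their levels) and within their range in the haploid (-0.0932), which argues against an extra copy in the haploid and is consistent with fewer C03 copies in the tetraploid plants. Sequence differences confined to a minority of C03 genes would leave the C03 median near 0. The lower quartile was 0.41 at meiosis and 0.43 at mitosis, and 88.5% and 85.7% of C03 genes were above 0. These values argue against differences in a minority of genes. Sequence differences that lower most C03 genes stay open. The interquartile range within C03 was above that of the other chromosomes at meiosis (0.84 against up to 0.76). It was inside their range at mitosis (0.85 against up to 0.91) and averaged over stages (0.70 against up to 0.72). A loss of C03 copies in the sampled tetraploid plants is thus a hypothesis that chromosome counts or DNA read depth could test, and a change of transcription along C03 was not tested.

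Genes that rose more than 16-fold in the tetraploid had a median of -1.88 in the haploid at mitosis. Library scaling would shift genes with no stage change by the same amount, but these had a median of 0.0135. TMM itself brings the bulk of genes near 0, so only the gap between the classes bears on scaling. A lower share of the cells that carry these transcripts would lower all of them alike and stays open, since the upper quartile was -0.49 with the class set by the tetraploid and -0.17 with the class set by the mean of both forms, but 0.18 with the class set by the haploid, and the interquartile range was 2.1 against 0.60 for genes with no stage change. Haploid anthers sampled earlier in the same course may also account for part of it. Genes that fell more than 16-fold were higher in the haploid at mitosis when classed by the tetraploid (median 1.46, 1.17 at the bound). Smaller classes set by 1 tetraploid library and measured on log2 CPM were also higher (0.62 in the lowest of 3 such classes). Genes classed by the haploid had a median of 0.01. That class shares the haploid mitosis libraries with the difference, which can pull its median down, and no haploid library was held out. The tests thus do not decide. A difference in pollen development between the forms stays open and untested.

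Of the 3776 steeply rising genes, 575 were called higher and 189 lower in the haploid already at meiosis. The counts were 257 and 260 of 2627 genes classed by the haploid, and 387 and 219 of 3194 classed by the mean of both forms. The excess thus depends on the class. In the class set by the tetraploid, 15.2% were called higher and 5.0% lower, both below the 17.2% and 19.7% of all genes outside C03. Many of these 3776 genes had few counts at meiosis, with 1271 at 0 counts in the haploid and 1293 in the tetraploid. Their median SE was 1.01, against 0.15 for genes within 0.25 between stages. The low shares called thus do not show that late genes differed less by ploidy. Chance low counts in the tetraploid meiosis libraries would leave no excess in a class set by 1 of them and tested without it, where calls higher were still at least 2.1 times the calls lower (399 and 190 in the lowest of 3 such classes). Of the 575, 529 had at least 3 counts per haploid meiosis library on average and stood at a median of 7.96% of their haploid mitosis level (interquartile range 3.06 to 18.4). Carry-over of haploid mitosis RNA would bring every abundant late gene at a like share, but 37 of 306 late genes with at least 100 CPM in each haploid mitosis library had 0 counts in all 3 haploid meiosis libraries, where that share would give at least 148 counts per library. Whether the late genes differ as a group at meiosis is thus not decided, and an earlier onset in the haploid or a wider range of bud stages was not tested.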

How the results depend on the processing

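The runs without C03 genes, and the alternatives for the C03 medians, the steeply rising genes and the overlaps, were chosen after seeing the data. Counts of calls stayed within 1.5 times under other size factors, no filter, DESeq2, FPKM with limma-trend, the replicate block and only the libraries compared. The larger side of the higher and lower calls turned under some of these for the ploidy difference at meiosis, both stage comparisons, the interaction and the average over stages, and for FPKM at a pseudocount of 0.1 it was 14088 higher and 21390 lower (stage in haploid), 17678 and 22302 (stage in tetraploid), 7164 and 9705 (interaction), and 12070 and 14288 (average); the cause was not tested. A 2-fold minimum lowered them by its construction, to 4905, 10212, 18198, 22486, 6911 and 5990 (ploidy at meiosis and mitosis, stage in haploid and tetraploid, interaction, average), and lowered the overlaps to 948 higher and 852 lower. Leaving out 1 library gave 17368 to 17709, 22491 to 22821, 31522 to 31682, 36160 to 36460, 14487 to 14797 and 23296 to 23587 calls, overlaps of 4593 to 4695 and 3706 to 3920, C03 medians of 0.82 to 0.86 and 0.87 to 0.90, and B share differences of -0.455 to -0.432, -1.03 to -0.946, -0.819 to -0.732 and -0.236 to -0.214 percentage points. Over the 12 alternatives in which it was taken, which leave out DESeq2, the C03 median was 0.56 to 0.86 and 0.56 to 0.90, lowest with FPKM. The median of steeply rising genes at mitosis was -1.98 to -1.59, the latter classed by the haploid. It was not taken in the runs that left out a haploid mitosis library. The B share difference between haploid and tetraploid reversed without C03 genes, to 0.503 and 0.470, since C03 counts are then out of the C share, and that between stages shrank to -0.0868 in the haploid and -0.0539 in the tetraploid. Replicate numbers do not pair the libraries (residual r of -0.0186 to 0.0147 over 18 same-number pairs), and the replicate block gave 19306, 24237, 32612, 36946, 15384 and 23989 calls. With libraries paired by replicate number, an exact sign-flip test gave p = 0.25 for the B share differences. This is the smallest possible p with so few pairs per comparison, so the test cannot decide whether these differences hold under the block. Of 375 values of named genes under alternatives, 374 kept their direction and call, and BcaC09g50824 lost its call without haploid meiosis replicate 2 (-9.04, adjusted p = 1, edgeR). Gene lists and term enrichment were not run, as IDs are not paired with names. Folds are bounds where a group had 0 counts in all its libraries, and genes with few counts are limited by depth.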

Other observations

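The test of gene runs by stage was chosen after the result was seen. A stretch of B01 held many genes that were higher at mitosis than at meiosis. The 50 consecutive tested genes from BcaB01g05996 to BcaB01g06069 had a median log2 fold change of 1.197 in the haploid and 1.53 in the tetraploid, the highest of 889 runs outside C03 in both forms. In 1000 shuffles of the genes, 95% of the highest medians were below 0.79 and 0.98. In the haploid 1 run passed that level and in the tetraploid 3 did. BcaB01g06051, the gene with the steepest fitted rise in the haploid, lies in this stretch.

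Unplaced genes took a larger share of counts at mitosis, 8.57% ± 0.0217 (SD, n = 3) in the haploid and 7.97% ± 0.0246 in the tetraploid, than at meiosis, 7.26% ± 0.0130 and 7.21% ± 0.0104. The most abundant gene of a library took 2.82% ± 0.0634 of counts in the haploid and 1.75% ± 0.0380 in the tetraploid at meiosis, and 1.52% ± 0.0334 and 1.03% ± 0.0216 at mitosis.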
